A study of Mus musculus with 13 samples.

How the data were processed

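The series holds 1 single-cell RNA-seq library and 12 bulk RNA-seq libraries of fetal mouse ovary. The single-cell library was made from 4 ovaries of 2 animals at embryonic day (E) 16.5, pooled after cryopreservation. These animals carried a tamoxifen-inducible Cre recombinase at the Hes1 locus, a gene switched on by Notch signaling, and a Cre-dependent nuclear reporter, Sun1-sfGFP, and tamoxifen was given at E10.5, so that cells expressing Hes1 near that day and their descendants carry the reporter. No sort for reporter-positive cells is stated in the labels. The bulk libraries were made from ovary pairs at E13.5. In 6 Notch-induced samples a Cre transgene driven by Nr5a1, a gene of somatic gonadal cells, was combined with a Cre-dependent Notch allele at the ROSA locus, and the 6 control samples carried the Cre transgene alone. Crosses ran in both directions, and each group is split by the genotype of the dam: 3 controls and 2 Notch-induced samples came from ROSA+/Notch dams, and 3 controls and 4 Notch-induced samples from Nr5a1-cre dams. Each bulk library is 1 ovary pair. The number of litters behind the 12 pairs is not given in the sources used here. Some pairs may be littermates, though the tests treat them as independent, and litter cannot be told apart from dam genotype.

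Both kinds of file are deposited as raw counts. For the single-cell library, UMI counts per feature and barcode were made with Cell Ranger 7.0.0 on mm10 per the submitters' processing notes, and the reporter is a feature of its own in the deposited count matrix. For the bulk libraries the deposited values are raw counts of reads per gene symbol, and the submitters' processing notes name Trim Galore 0.6.10, STAR 2.6.0c, SAMtools 1.18 and featureCounts of Subread 2.0.6 on mm10. The gene annotation used for counting and the strand setting are not given in the sources used here, so reads of overlapping and antisense genes cannot be told apart, and counts of near-identical copies are uncertain. Gene positions are from GENCODE vM21, which annotates the mm10 assembly.

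The bulk table holds 49997 genes, of which 21437 passed the expression filter of edgeR (filterByExpr on group). Total counts ranged from 66653146 to 193345417 per library, which for genes of this study leaves the spread between libraries, not counting error, as the main limit. Counts were scaled by TMM and tested with edgeR 4.0.16, using the quasi-likelihood test with dam genotype and group as terms and Benjamini-Hochberg (BH) adjustment. A gene was called at an adjusted p under 0.05. The dam effect came from the fit with dam genotype and group, and the dam by genotype interaction from a fit with their product. Normalised CPM values are counts per TMM-scaled library size in CPM. Positive log2 fold changes mean higher in Notch-induced ovaries, and those from all 12 libraries are given with their standard errors. On simulated counts with the means and library sizes of these libraries, over 21099 genes, the test recovered 51.5% of genes changed by 0.5 on the log2 scale, 81.8% of those changed by 1 and 98.4% of those changed by 2, and it called 10 of 20903 unchanged genes. Only 200 genes were set to change, without dam or litter effects, while 7553 were called in the data. These rates therefore need not hold for the real comparison.

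Lists for 31 pathways and cell types were fixed before the data were examined. They were tested with camera (limma 3.58.1) at a preset correlation of 0.01 between genes, with BH adjustment over the lists. Camera with an estimated correlation and fry were run beside it. The preset test treats the genes of a list as nearly independent and so gives small p-values where genes vary together between libraries. Genes named in the text follow a rule fixed before the data were examined. It takes Notch1 and the tested Notch target genes, the 12 largest rises and the 12 largest falls among called genes with a mean log2 CPM of at least 1 and the same sign within each dam genotype, up to 4 members with the smallest p of each list described, and the 6 smallest p for the dam effect and for the interaction. Predicted genes without a name were left out of the largest changes, which skipped 0 rises and 1 fall. Some genes that this rule or the class rankings pick are not reported here, and they stay in the counts of changed genes. Counts over examined genes cover most genes picked by the rule and the others named in the text, whether or not their values are given. Other genes are said to be chosen after their values were seen.

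The single-cell matrix holds 13994 barcodes and 32286 features. Barcodes with at least 500 genes and a mitochondrial share of at most 10% were kept, which gave 7668. Scrublet, run through Scanpy 1.11.5, called 145 of them doublets (1.89%), and 7523 cells were analysed, with a median of 8820 UMIs and 3321 genes. Counts were normalised to 10000 per cell, and 2000 variable genes, 40 principal components and 15 neighbours entered Leiden clustering at resolution 1.0. Clusters were named from markers fixed before the data were examined, by the mean log2 ratio of marker CPM in a cluster to the mean of the other clusters, with 10 CPM added to both. A name needed a score of at least 0.5, a margin of 0.3 over the next cell type and 3 markers detected in 10% of its cells. A cluster also stayed unnamed where its 10 top genes by ratio held more markers of another type, if at least 3 markers of that type were detected. These thresholds were set after the data were seen, and a stricter rule without this last condition was tried and not kept. Levels per class are UMIs of a gene relative to all UMIs of the class, as CPM, with exact Poisson 95% intervals, and shares of cells have exact Clopper-Pearson 95% intervals. With 1 library, all these intervals cover counting error only, and no test between classes is reported. Because classes differ in depth, shares of cells with a reporter UMI are also given after thinning each cell to 3000 UMIs and leaving out shallower cells. A gene set was made for each class from up to 50 genes with at least 50 CPM in it and at least 2 times the level of the next class, and was tested in the bulk libraries with camera.

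Alternatives covered the dam term, DESeq2 1.42.0, limma-voom, other scalings and filters, the replicate number as a block, each dam genotype alone, each library left out in turn, the cell filters, doublets and clustering resolution. Chi-square comparisons of counts showed no pair of bulk libraries alike within sampling noise. Analyses were run in R 4.3.3 and Python 3.11.15.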

Results

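The data comprise 7523 single cells of E16.5 ovary carrying a Hes1-lineage reporter, and 12 bulk libraries of E13.5 ovary pairs, 6 control and 6 Notch-induced. The bulk libraries held between 66653146 and 193345417 counts, and the single-cell matrix held 106008542 UMIs in 13994 barcodes. The series title places both experiments in the question of how the interstitial lineage of the fetal ovary is specified and how it responds to the level of Notch signaling.

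Interstitial progenitor-like cells made up the largest class of the E16.5 ovary, with 44.2% of 7523 cells (95% interval 43.1 to 45.4). Pre-granulosa-like cells, the supporting cells that will surround oocytes, made up 23.6% (22.7 to 24.6) and germ-like cells 5.12% (4.63 to 5.64). Endothelial-like cells were 3.10%, surface epithelial-like cells 2.25%, perivascular or smooth muscle-like cells 2.18%, immune-like cells 1.28% and erythroid-like cells 0.705%. The genes with the largest ratio to the next class were Syt1, Sfrp1 and Sgcd in interstitial progenitor-like cells, and Dync1i1, Gm35533 and Clu in pre-granulosa-like cells. Germ-like cells were led by Smc1b, Sycp3 and Syce3, which encode proteins of meiotic chromosome axes and synapsis. Flt1, Cdh5 and Cldn5 led endothelial-like cells, Ndufa4l2 and Rgs5 perivascular-like cells, and Upk3b, Muc16 and Krt19 surface epithelial-like cells. Hba-a1, Hbb-bs and Hbb-bt, the adult globins, led erythroid-like cells. The immune-like class was led by S100a9, Camp and S100a8, genes of neutrophils, which come from its cluster of 60 cells, while its other cluster of 36 cells was led by the macrophage genes C1qa, Tyrobp and Aif1.

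Of the 21 clusters, 19 were named. The largest interstitial progenitor-like cluster had 1470 cells, and those of 530 and 117 cells were led by the proliferation genes Pclaf, Prc1 and Top2a and by Cenpa, Ccnb2 and Cdc20. The 2 unnamed clusters held 17.5% of cells. One of them had 807 cells with a median of 1118 UMIs, and the other had 509 cells led by Kif26b, Tagln and Caln1. A stricter naming rule, tried and set aside after the data were seen, left this cluster of 1470 cells and the Bmpr1b-led pre-granulosa-like cluster of 207 cells unnamed, so that interstitial progenitor-like cells made up 24.7%, pre-granulosa-like cells 20.9% and unnamed cells 39.8%. With a mitochondrial limit of 5% the pre-granulosa-like share was 12.03% and the interstitial progenitor-like share 59.9%, and the 580 cells then named pre-granulosa-like had a median of 1770 UMIs, as the pre-granulosa-like clusters, with median mitochondrial shares from 6.43% to 7.55%, are largely removed.

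Reporter UMIs were most frequent in endothelial-like cells. Of 233 such cells, 85 (36.5%, 95% interval 30.3 to 43.0) held at least 1, at 86.2 CPM (78.3 to 94.6). Perivascular or smooth muscle-like cells followed at 15.1 CPM (9.49 to 22.9), interstitial progenitor-like cells at 8.07 CPM (7.09 to 9.14) and pre-granulosa-like cells at 3.92 CPM (3.28 to 4.64). By share of cells, these 3 classes had 5.49%, 3.22% and 3.04%. Surface epithelial-like cells, the deepest class at a median of 21321 UMIs, had 3.55% at 1.55 CPM. Over all analysed cells the share was 3.85% (3.43 to 4.31).

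Depth differed between classes, with median UMIs of 11406 in endothelial-like, 8531 in interstitial progenitor-like and 13181 in pre-granulosa-like cells. After thinning to 3000 UMIs per cell, the shares were 20.5% (15.02 to 27.0) of 190 endothelial-like cells, 3.40% (1.11 to 7.76) of 147 perivascular-like cells, 1.82% (1.39 to 2.35) of 3236 interstitial progenitor-like cells and 0.744% (0.397 to 1.27) of 1747 pre-granulosa-like cells. Thinning left out 43, 17, 92 and 32 shallower cells of these classes. With a mitochondrial limit of 5% the interstitial progenitor-like and pre-granulosa-like shares were both 1.30%. There 350 of the 580 pre-granulosa-like cells were too shallow to thin. Germ-like cells, of another lineage, had 3 of 385 cells with a reporter UMI (0.779%) at a median of 2391 UMIs and 2.21 CPM (0.887 to 4.55). Thinned, 2 of 171 germ-like cells (1.17%, 0.142 to 4.16) held one, an interval that spans the pre-granulosa-like and interstitial progenitor-like shares. Erythroid-like cells had 0 of 53 at a median of 4886 UMIs, which allows a share of up to 5.66% by 3 counts and 6.72% by the exact interval for cells with a reporter UMI and sets no limit on cells that carry the reporter. Barcodes under the gene minimum, with a median mitochondrial share of 55.8%, had 1.96 CPM (0.939 to 3.60). The interval of pre-granulosa-like cells overlaps both that of germ-like cells and that of these barcodes. Yet 27 of them held 2 or more reporter UMIs, where spreading at random over the UMIs of the class would give 7.60, so free RNA spread at random does not account for all of their reporter UMIs. Germ-like cells had 2 such cells against 0.176.

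Within classes, the reporter share was 64.3% (44.1 to 81.4) in the 28 endothelial-like cells led by Gja4, a connexin of arterial endothelium, 41.6% (33.6 to 50.0) in the 149 led by Pcdh17, Piezo2 and Aplnr, and 8.93% (2.96 to 19.6) in the 56 led by Ly6d, Ctla2a and Stmn2, whose median was 1342 UMIs. Among pre-granulosa-like clusters it was 7.25% (4.11 to 11.7) in the 207 cells led by Kcnip4, Bmpr1b and Rmst, at 9.23 CPM (6.59 to 12.6), and 2.16% (1.22 to 3.54) in the 693 cells led by Calb1, Lgr5 and Gng13. The cluster of 207 cells held 40 of the 134 reporter UMIs of the class, and its name is less sure, since its 10 top genes include Pax8, a marker of rete and tubule epithelium, and no pre-granulosa marker. These clusters were singled out after their values were seen.

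**Figure D1:**
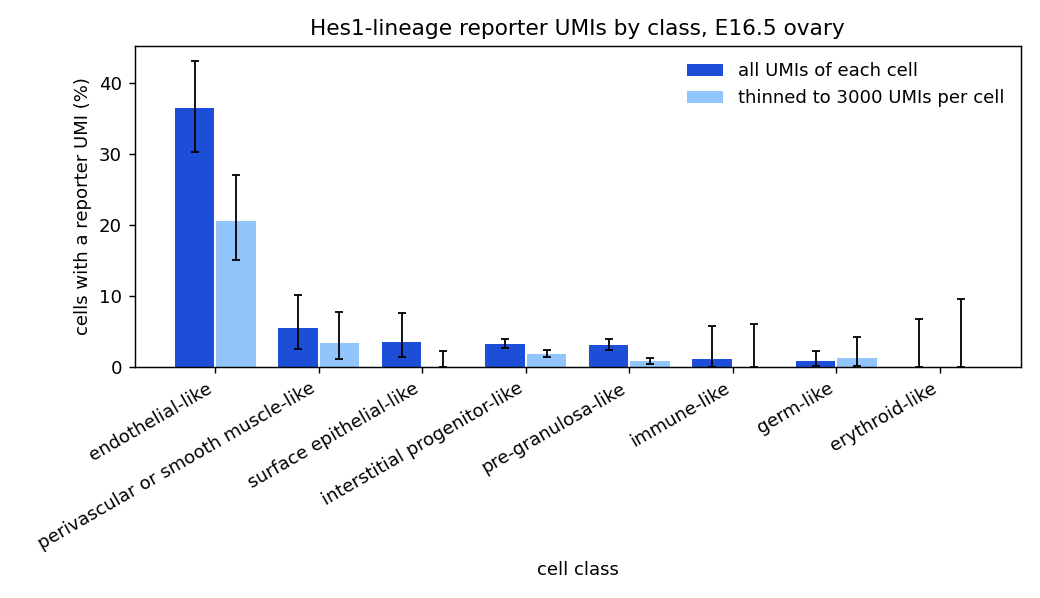
Share of cells with at least 1 reporter UMI (%, vertical axis) in each cell class (horizontal axis), with all UMIs (dark bars) and after thinning to 3000 UMIs per cell (light bars), and exact 95% intervals that cover counting error only. Endothelial-like cells stand at 36.5% before and 20.5% after thinning, above every other class.

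Components of the Notch pathway were unevenly spread over the classes. Hes1 was highest in pre-granulosa-like cells (256 CPM, 250 to 261) and perivascular-like cells (199 CPM, 177 to 223), against 94.1 CPM in interstitial progenitor-like cells (90.7 to 97.6) and 91.5 CPM in endothelial-like cells. Perivascular-like cells had the highest levels of Notch3 (235 CPM), Heyl (143 CPM), Jag1 (56.4 CPM) and Hey2 (37.2 CPM), a receptor, a ligand and a pair of target transcription factors. Endothelial-like cells had the highest levels of Notch1 (158 CPM), of the ligand Dll4 (62.7 CPM) and of Mfng (98.4 CPM), a glycosyltransferase that modifies Notch receptors. Nrarp, a feedback inhibitor of Notch signaling, stood at 66.2 CPM (59.3 to 73.7) in endothelial-like and 61.9 CPM (49.8 to 76.1) in perivascular-like cells, with overlapping intervals. Dlk1, a non-canonical ligand, was highest among named classes in interstitial progenitor-like cells, at 506 CPM. In pre-granulosa-like cells, where Hes1 was highest, Heyl (1.55 CPM), Hey2 (0.672 CPM) and Nrarp (0.234 CPM) were low, while Dtx1 had its highest level there, at 24.7 CPM (23.1 to 26.4).

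Notch1 was 2.20-fold higher in Notch-induced than in control E13.5 ovaries, at 169 ± 6.05 against 77.4 ± 8.65 CPM (SD, n = 6 each), a log2 fold change of 1.14 ± 0.07 (edgeR quasi-likelihood test, BH adjusted p = 3.3e-08). The counts do not separate transcripts of the induced Notch allele from those of the endogenous gene on chromosome 2 (26457903 to 26516663, mm10). Among 9 Notch target genes tested, 6 rose and 1 fell. The Hairy-related transcription factors Hey2, Heyl and Hey1 rose by 3.73 ± 0.24, 3.68 ± 0.18 and 1.60 ± 0.07 on the log2 scale, Nrarp by 1.81 ± 0.12, the receptor Notch3 by 1.31 ± 0.10 and Hes1 by 0.82 ± 0.07. Dtx1, a ubiquitin ligase of the pathway, fell by 0.67 ± 0.13 on the log2 scale. Hes5 (-0.32 ± 0.14) and Hes7 (0.29 ± 0.26) did not pass the test. Adjusted over the list alone, 6 rose and 2 fell. With ROSA+/Notch dams only, Dtx1 did not pass (edgeR BH adjusted p = 0.183).

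**Figure D2:**
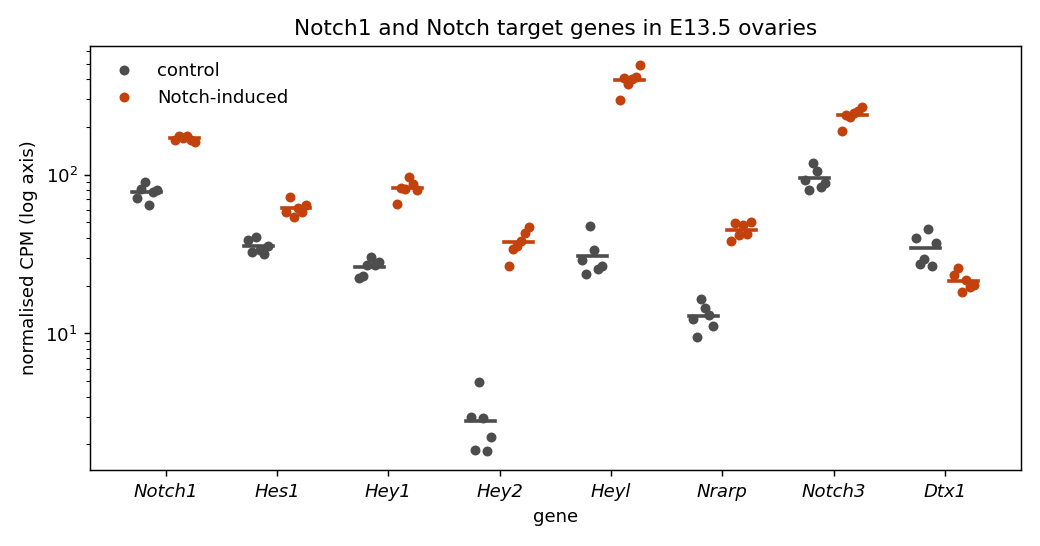
Normalised CPM (vertical log axis) of Notch1 and 7 Notch target genes (horizontal axis) in 6 control (grey) and 6 Notch-induced (orange) libraries, with group means as lines. Heyl rose from a mean of 30.9 to 396 CPM and Hey2 from 2.79 to 37.4 CPM.

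In all, 3715 genes were higher and 3838 lower in Notch-induced ovaries among 21437 tested (edgeR, BH adjusted p under 0.05). At least 2-fold changes numbered 707 higher and 753 lower, and at least 4-fold changes 174 and 98. The control and Notch-induced values did not overlap for 18.3% of genes, against 0.216% by chance for 6 against 6. Of 7553 called genes, 7516 had the same sign within both dam genotypes. They were called from these same libraries, which favours such agreement. The log2 fold changes within each dam genotype correlated at 0.694 across genes and at 0.896 for called genes. With ROSA+/Notch dams only, the counts were 1101 and 1156. TMM factors lay between 1.01 and 1.03 in control and between 0.960 and 0.996 in Notch-induced libraries. Mitochondrial genes held 0.735% to 1.12% of counts in control and 0.876% to 1.80% in Notch-induced libraries. Whether library quality plays a part was not tested.

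The largest rise was in Lefty2, a secreted inhibitor of Nodal signaling, by 7.22 ± 0.38 on the log2 scale to 32.4 ± 13.2 CPM, and Lefty1 rose by 4.30 ± 0.30. Col28a1, which encodes a collagen, rose by 4.83 ± 0.17, Iqsec3 by 5.09 ± 0.30, Chst9, a sulfotransferase, by 4.46 ± 0.25, AW011738 by 4.28 ± 0.23, Cnmd, chondromodulin, by 4.12 ± 0.49, Zfp663 by 3.90 ± 0.29 and Vgll3, a cofactor of TEAD factors, by 3.65 ± 0.27. Hey2 and Heyl were also among the 12 largest rises. The largest fall was in Mpo, the myeloperoxidase of neutrophils, by -4.85 ± 0.80, with control values that ranged up to 65.7 CPM in 1 library. Calb1, a calcium-binding protein, changed by -3.96 ± 0.30, the receptor tyrosine kinase Ret by -3.01 ± 0.22, Ablim3 by -2.68 ± 0.24, the ion channel Asic4 by -2.65 ± 0.31 and Hsd3b1, an enzyme of steroid synthesis, by -2.51 ± 0.20. Trim66 (-2.45 ± 0.19), Enpp2, which encodes autotaxin (-2.43 ± 0.20), Atp8b4 (-2.42 ± 0.28), the transcription factors Bhlhe41 (-2.38 ± 0.20) and Hand1 (-2.31 ± 0.22), and Rilp (-2.33 ± 0.19) complete the 12 largest falls.

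Genes of stromal and vascular cells rose. In the extracellular matrix list 19 of 24 rose and 0 fell, among them the basement membrane genes Nid1 (2.01 ± 0.09), Col4a1 (1.36 ± 0.09) and Lamb1 (0.69 ± 0.05) and the proteoglycan Vcan (1.49 ± 0.08). In the interstitial progenitor list 16 of 22 rose and 0 fell, with Nr2f2, the transcription factor COUP-TFII, at 1.00 ± 0.07, Ebf1 at 1.66 ± 0.16, Wnt5a at 0.76 ± 0.08 and Mgp at 1.68 ± 0.19. In the perivascular and smooth muscle list 9 of 13 rose and 0 fell, with the PDGF receptor Pdgfrb at 1.76 ± 0.13, the potassium channel subunits Abcc9 at 2.41 ± 0.19 and Kcnj8 at 2.51 ± 0.26, and Cspg4, the NG2 proteoglycan of pericytes, at 0.76 ± 0.07. In the endothelial list 15 of 17 rose and 0 fell by smaller amounts, with Tek at 0.67 ± 0.11, Emcn at 0.59 ± 0.10, Aplnr at 0.62 ± 0.11 and Esam at 0.48 ± 0.10. With ROSA+/Notch dams only, Tek (0.54), Aplnr (0.59) and Esam (0.51) did not pass (edgeR BH adjusted p = 0.101, 0.066 and 0.0831). Of 15 immune genes 7 rose and 0 fell, led by the macrophage genes Mrc1 (1.01 ± 0.12) and Cx3cr1 (0.64 ± 0.09), and of 20 cell cycle genes 9 rose and 1 fell, with Cdk1 at 0.36 ± 0.05 and Aurkb at 0.34 ± 0.05. Each of these lists, and the Notch target list, passed camera with the preset correlation, with BH adjusted p from 6.86e-10 for extracellular matrix to 0.00334 for cell cycle. None passed with an estimated correlation, where the adjusted p = 0.471 for cell cycle and 0.419 for the other lists named here.

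Genes of the pre-granulosa and steroidogenic lists fell. In the pre-granulosa list 17 of 22 fell and 3 rose. The activin antagonist Fst fell by 1.47 ± 0.11 on the log2 scale, from 158 ± 19.2 to 56.7 ± 10.4 CPM, and Irx3 by 1.51 ± 0.13, Msx1 by 1.32 ± 0.08 and Wnt6 by 1.20 ± 0.10. The 3 that rose, Foxl2, Rspo1 and Hsd17b1, at 0.54 ± 0.09, 0.25 ± 0.05 and 1.01 ± 0.32, were named because they go against the list, after their values were seen. Hsd17b1 lost its call without control replicate 4, 5 or 6 or Notch-induced replicate 2 (0.92, 0.88, 0.87 and 1.03, edgeR BH adjusted p from 0.055 to 0.0818) and changed by 0.08 with ROSA+/Notch dams only, where Rspo1 (0.24) did not pass either (adjusted p = 0.0687). In the steroidogenic list 11 of 19 fell and 2 rose, with Hsd3b1 as above, Nr0b1, the nuclear receptor DAX1, at -1.39 ± 0.15, the electron carrier reductase Fdxr at -0.998 ± 0.09, and Nr5a1, whose promoter drives the Cre transgene, at -0.86 ± 0.08. The list of adrenal cortex and chromaffin cells also lay lower, with mean levels from -0.97 to -0.61 log2 CPM in Notch-induced and -0.33 to 0.07 in control libraries, but did not pass (camera, preset correlation, BH adjusted p = 0.173). Of 15 Wnt/beta-catenin targets 7 fell and 1 rose, with Rnf43, Lgr5 and Sp5 at -1.29 ± 0.13, -1.31 ± 0.15 and -1.30 ± 0.15, and of 12 hypoxia response genes 6 fell and 0 rose, with Adm at -1.61 ± 0.16 and Bnip3 at -0.69 ± 0.08. Camera with the preset correlation gave BH adjusted p from 6.1e-06 for pre-granulosa genes to 0.00902 for Wnt targets, and an estimated correlation gave adjusted p = 0.419 for each of these 4 lists.

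Of 21 meiotic germ cell genes 8 fell and 0 rose, with the cohesin subunits Rec8 at -1.13 ± 0.25 and Stag3 at -0.51 ± 0.15, the recombinase Dmc1 at -0.56 ± 0.16 and Taf7l at -1.35 ± 0.39 (camera, preset correlation, BH adjusted p = 0.0258, and adjusted p = 0.640 with an estimated correlation). The list did not pass with fry (adjusted p = 0.136). Without Notch-induced replicate 1 or 2, Taf7l (-1.04 and -1.06) and Dmc1 (-0.46 and -0.49) lost their calls, as did Dmc1 (-0.46) and Stag3 (-0.39) without control replicate 5 (edgeR BH adjusted p from 0.0534 to 0.0666). The fall was uneven between dams. The median change of the list was -1.03 with ROSA+/Notch dams (camera BH adjusted p = 1.42e-12 with the preset and 0.601 with an estimated correlation) and -0.10 with Nr5a1-cre dams (adjusted p = 0.927 with the preset correlation), where Taf7l, Dmc1 and Stag3 did not pass, and the difference itself had a median of 1.20 (camera adjusted p = 6.83e-13 with the preset and 0.406 with an estimated correlation). The mean level of the list was 4.22 ± 0.17 log2 CPM (SD, n = 3) in controls of ROSA+/Notch dams and 3.12 ± 0.57 (n = 3) in controls of Nr5a1-cre dams, against 2.94 (n = 2) and 3.11 ± 0.24 (n = 4) in Notch-induced ovaries. Among controls of Nr5a1-cre dams, replicate 5 stood apart at 3.77, while replicates 4 and 6, at 2.71 and 2.87, lay below the Notch-induced mean of those dams. The other 19 lists did not pass at the preset correlation, with BH adjusted p from 0.0843 for Notch receptors, ligands and cofactors to 0.585 for mitotic and pluripotency germ cell genes. Among the receptors and ligands, Jag1 rose by 2.42 ± 0.20 and Notch2 by 0.47 ± 0.05.

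**Figure D3:**
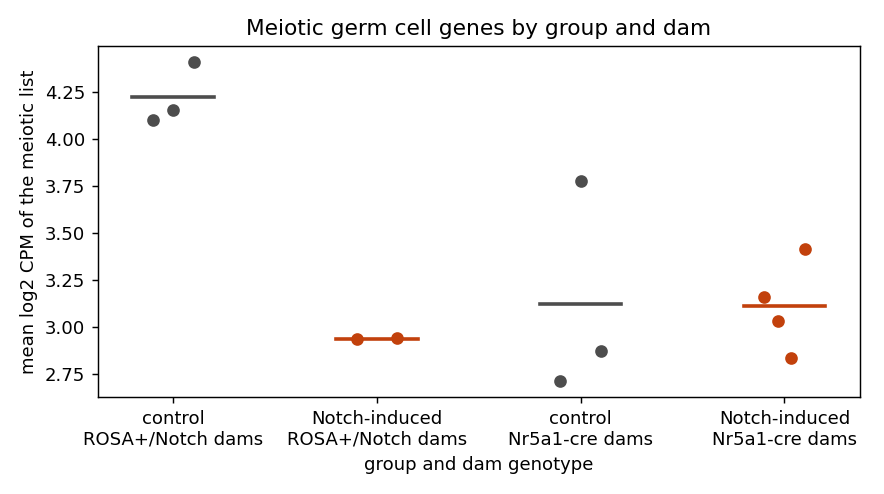
Mean log2 CPM of 21 meiotic germ cell genes (vertical axis, not starting at 0) in each of the 12 bulk libraries by group and dam genotype (horizontal axis), with means as lines. Controls of ROSA+/Notch dams lie between 4.10 and 4.41, controls of Nr5a1-cre dams between 2.71 and 3.77, and the Notch-induced libraries between 2.84 and 3.42.

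Gene sets taken from the E16.5 cell classes moved apart in the E13.5 bulk libraries. Of 48 perivascular-like genes tested, 39 rose and 1 fell (median 1.15), of 49 endothelial-like genes 32 rose and 0 fell (median 0.41), and of 50 interstitial progenitor-like genes 29 rose and 3 fell (median 0.36). Of 49 erythroid-like genes 37 fell and 0 rose (median -0.72), of 49 pre-granulosa-like genes 32 fell and 10 rose (median -0.62), of 50 surface epithelial-like genes 26 fell and 7 rose (median -0.42), and of 49 germ-like genes 15 fell and 1 rose (median -0.41). These 7 sets passed camera with the preset correlation, with BH adjusted p from 1.54e-18 to 0.00021, and none passed with an estimated correlation, where adjusted p lay between 0.367 and 0.523. Immune-like genes had a median of 0.02 and did not pass (camera adjusted p = 0.108). With fry the germ-like set did not pass either (adjusted p = 0.0895). The germ-like set had a median of -0.99 with ROSA+/Notch dams (camera adjusted p = 4.36e-23 with the preset and 0.489 with an estimated correlation) and -0.02 with Nr5a1-cre dams (adjusted p = 0.701 with the preset correlation), and the difference itself passed with the preset and not with an estimated correlation (adjusted p = 2.735e-19 and 0.668) or with fry (0.209).

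Dam genotype alone changed no gene past the threshold (0 genes, edgeR BH adjusted p under 0.05), with 1382 genes at an unadjusted p under 0.05 and 16 genes by DESeq2. For the dam effect 4 gene lists and 4 class sets passed camera with the preset correlation, and 0 with an estimated correlation or fry. The smallest p-values, all at an adjusted p of 0.449 in edgeR, belonged to Afp, alpha-fetoprotein (3.40 ± 0.63, Nr5a1-cre minus ROSA+/Notch dams), Serpina6 (3.51 ± 0.67), Apoa1 (1.17 ± 0.22), Rbm3 (0.29 ± 0.06), Thsd7b (0.32 ± 0.06) and Lrrc4c (0.49 ± 0.10).

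By the test for each gene, the effect of Notch induction differed between dam genotypes for 1 gene, Lonrf3, a RING finger gene on chromosome X (36328353 to 36362341, mm10). Lonrf3 rose from 5.06 ± 0.52 (n = 3) to 9.83 ± 0.32 CPM (n = 2) with ROSA+/Notch dams and from 2.15 ± 0.08 (n = 3) to 13.3 ± 1.07 CPM (n = 4) with Nr5a1-cre dams, an interaction of 1.67 ± 0.17 on the log2 scale (edgeR BH adjusted p = 0.00333). Without Notch-induced replicate 1 or 2, the only Notch-induced libraries of ROSA+/Notch dams, the interaction was 1.71 and 1.64 with edgeR adjusted p = 0.062 and 0.0896, and the remaining library of that cell was taken to vary like the others. The next smallest p-values, at edgeR adjusted p from 0.236 to 0.28, belonged to 4933403O08Rik, the synaptonemal complex gene Sycp2 (2.17 ± 0.36), Xlr4b, Gm14165 and Gm8730. At an unadjusted p under 0.05 there were 2296 genes, and DESeq2 called 184. Without control replicate 5 edgeR called 57, among them the meiotic genes Sycp1, Sycp2 and Sycp3. For the interaction 10 gene lists and 4 class sets passed camera with the preset correlation, and 0 with an estimated correlation or fry.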

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

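All weighings in this part rest on tests chosen after the results were seen, except the splits of the libraries into other groups, which were set before the data were examined. Relabelling the 12 bulk libraries, taken as independent, excludes chance for the counts of changed genes. In 1 of 100 splits drawn of 462, the real one, were there as many as 3715 higher genes, and the highest other split had 1. The same held for the 3838 lower genes, in 1 of 100 splits, with 4 in the highest other split. For the number of gene lists that passed at the preset correlation chance is not excluded: 20 of 100 splits gave at least 12, and the highest other gave 17. The same holds for the single-cell class sets, where 17 of 100 splits gave at least 7 and the highest other gave 8. Both counts include the real split. Splits with unequal numbers of controls on each side also keep part of the difference between the groups, so they are not a pure picture of chance. For genes that differ by dam the splits decide nothing, since a real count of 0 is reached in 100 of 100 splits whatever the data, the highest other having 10.

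The rise of vascular and stromal genes with the fall of pre-granulosa genes was set against a change in tissue make-up. A lower share of pre-granulosa cells with no other change would raise the genes of all other classes alike. Yet the erythroid-like set changed by -0.79 (95% interval -1.14 to -0.39) and the perivascular-like set by 1.17 (0.89 to 1.42), which argues against this form. The interstitial progenitor-like set, at 0.39 (0.25 to 0.54), also lay below the perivascular-like set. The erythroid list fixed beforehand did not pass (camera, preset correlation, BH adjusted p = 0.143). More mesonephric tissue in the Notch-induced samples would raise genes of its tubules, and these changed by -0.27 (-0.41 to -0.14), while the list of mesonephric and ligament mesenchyme changed by 0.36 (0.14 to 0.60). A lower pre-granulosa share together with other changes of make-up stays open, as does more mesonephric or ligament mesenchyme. A changed number of perivascular cells and changed expression within cells also stay open, all as hypotheses.

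The change of Lonrf3 differed between dam genotypes by 1.67 on the log2 scale. X-linked variants of the parental strains stay open. Among the 20 genes with the smallest interaction p, 18 have a chromosome, and 6 of these (33.3%) are X-linked. The share is 4.05% for all tested genes with a chromosome (Fisher's exact test, 1-sided, p = 5.32e-05). The 6 include Lonrf3 itself and Xlr4a, Xlr4b and Xlr3c of 1 gene family, so they are not independent. Xlr4b, like Sycp2, was highest in controls of ROSA+/Notch dams (3.93 and 7.42 CPM), unlike Lonrf3. The share therefore cannot decide the cause for Lonrf3. Dependence on 1 library also stays open, because removal of either of 2 libraries ended the call, through a cell left with 1 sample, while the interaction stayed between 1.59 and 1.73 whichever of the 12 libraries was left out. Litters at different stages of meiosis, as far as the meiotic list reads them, are argued against as the whole cause for Lonrf3. Its interaction was 1.58 ± 0.26 with the level of that list as a covariate, although its edgeR adjusted p was then 0.534 with the larger standard error. The list holds germ cell genes measured after induction, so litter age as seen in other cells was not tested. With the same covariate the Sycp2 interaction went from 2.17 ± 0.36 to 0.99 ± 0.27, so for Sycp2 a part played by meiotic stage stays open. The parental direction itself was not tested apart from these, and litter cannot be told apart from dam genotype here.

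Reporter UMIs in endothelial-like cells were set against free RNA and depth. The lower bound in endothelial-like cells was 78.3 CPM and the upper bound in barcodes under the gene minimum was 3.60 CPM. Those barcodes, with a median mitochondrial share of 55.8%, may hold damaged cells and so measure free RNA poorly. Free RNA spread evenly over droplets is argued against by the other named classes, whose upper bounds were at most 22.9 CPM. More UMIs per cell are argued against, as the thinned share was 20.5% (lower bound 15.02) in endothelial-like cells and had an upper bound of 2.35% in interstitial progenitor-like cells. Hes1 activity of endothelial cells at E10.5 is left as a hypothesis, and unequal expression of the reporter between cell types was not tested.

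Barcodes left out by the filters, which enter no comparison, held 56 reporter UMIs in 47 of 6326 barcodes, or 3.63 CPM.

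Single libraries stood far from the rest of their group in 17 of 200 groups of examined genes (8.5%), where chance gives about 1 in 20. In control replicate 3, Hey2 was at 4.96 CPM against at most 2.998 in the other controls, Jag1 at 21.2 against 13.1, Abcc9 at 33.2 against 20.8 and Kcnj8 at 15.3 against 8.71, all toward the Notch-induced values, and Ablim3 was at 26.6 against at least 39.2. Control replicate 3 was the control nearest to the Notch-induced mean for 26.9% of called genes. Gm8730, a predicted gene whose reads can be shared with near-identical copies, was at 13.3 CPM in control replicate 3 and between 13.4 and 18.8 in Notch-induced libraries of Nr5a1-cre dams, against 210 to 288 in the rest. In Notch-induced replicate 1, Col4a1 was at 2111 CPM against at least 2475, Calb1 at 2.09 against at most 1.06, Ablim3 at 12.4 against 5.82, Trim66 at 7.18 against 3.73 and Rilp at 1.47 against 0.982. In Notch-induced replicate 6, Iqsec3 was at 17.1 CPM against 9.45, Taf7l at 10.54 against 5.13 and Afp at 3.75 against 1.20. In control replicate 6, Mpo was at 65.7 CPM against 19.2 and Atp8b4 at 6.95 against 4.499, and in control replicate 5 Lefty2 was at 0.499 against 0.243.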

How the results depend on the processing

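The tests of lists within 1 dam genotype and of Lonrf3 and Sycp2 with a meiotic covariate, and the stricter naming of clusters, were chosen after seeing the data, and the others before. No result reversed. Notch1 passed in all alternatives, at 1.09 to 1.175 with 1 library left out. Of 88 examined genes with a fold change, not all of them named in the text, the calls of 15 changed in any setting, 12 of them with ROSA+/Notch dams only, where 3 controls and 2 Notch-induced samples remain. There 1101 genes were higher and 1156 lower, from fewer samples. Counts stayed within 1.5 times in the other settings, from 3085 to 3851 higher and 3145 to 3916 lower with 1 library left out. Replicate numbers do not pair the libraries, with correlations of same-numbered libraries from -0.089 to 0.038, and no library correlated best with its own number. With the number as a block, 2827 genes were higher and 2661 lower, and Taf7l (-1.20 against -1.35, adjusted p = 0.0519) and Hsd17b1 (0.93 against 1.01, adjusted p = 0.0781) lost their calls with folds about as large. Genes that differ by dam numbered 16 with DESeq2 and 1 without a filter, and stayed at 0 with each library left out. Genes with an interaction numbered 184 with DESeq2 and 31 without a filter, and from 0 to 57 with 1 library left out: 0 without Notch-induced replicate 1 or 2, 4 without control replicate 3 and 57 without control replicate 5. The cause was not tested. For gene lists, 0 passed with an estimated correlation and 21 with fry, which asks another question, against 12. The meiotic list, 1 of those 12, did not pass with fry (adjusted p = 0.136). For class sets, 0 passed with an estimated correlation, against 7. With fry the germ-like and immune-like sets did not pass (adjusted p = 0.0895 and 0.22), and the other sets did (5.89e-05 to 0.00855). Within 1 dam genotype, 11 lists passed with ROSA+/Notch and 12 with Nr5a1-cre dams, and 7 class sets with each, all at the preset correlation, and 0 with an estimated one. Fry called 0 lists and 1 class set with ROSA+/Notch dams, and 18 lists and 4 class sets with Nr5a1-cre dams. The 7 class sets at the preset correlation were not the same. The germ-like set passed with ROSA+/Notch dams alone and the immune-like set with Nr5a1-cre dams alone, and the difference between dams passed at the preset correlation for the germ-like set but not for the immune-like set (camera adjusted p = 0.0978). With at least 1000 genes per cell, shares were 49.9% interstitial progenitor-like, 28.8% pre-granulosa-like, 8.61% unnamed, 3.47% surface epithelial-like, 3.11% germ-like, 0.913% immune-like and 0.387% erythroid-like. With mitochondrial shares up to 5% they were 59.9% interstitial progenitor-like, 12.03% pre-granulosa-like and 13.1% unnamed. At Leiden resolution 2.0 they were 45.9% interstitial progenitor-like, 15.1% unnamed and 3.004% surface epithelial-like, which was 2.93% with doublets kept. With stricter naming they were 24.7% interstitial progenitor-like, 20.9% pre-granulosa-like and 39.8% unnamed, since 2 clusters lose their names. Thinned reporter shares were then 1.99% in interstitial progenitor-like and 0.712% in pre-granulosa-like cells, within the intervals of 1.82% and 0.744%, and the unthinned pre-granulosa-like share was 2.48%, against 3.04%. Thinned reporter shares at the 5% limit were 1.30% in interstitial progenitor-like, 1.30% in pre-granulosa-like and 0% in germ-like cells, where 350 of the 580 cells then named pre-granulosa-like were too shallow to thin. Unthinned they were 36.5% endothelial-like, 3.22% interstitial progenitor-like, 3.04% pre-granulosa-like and 3.55% surface epithelial-like. For at least 2 UMIs they were 4.21% endothelial-like, 0.587% interstitial progenitor-like, 0.114% pre-granulosa-like and 0% germ-like, from the stricter count. The number of cells limits the reporter shares of immune-like and erythroid-like cells, with 96 and 53 cells. Depth limits that of germ-like cells, where 214 of 385 cells were too shallow to thin.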

Other observations

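Genes outside the lists that passed also changed in Notch-induced ovaries, by edgeR's test for each gene. Bmp4, a signaling ligand, rose by 2.68 ± 0.16 and Inhbb, the beta B subunit of activin and inhibin, by 1.47 ± 0.09, in a TGF-beta list where 9 of 22 rose and 6 fell. The cell cycle inhibitors Cdkn1c, an imprinted gene, and Cdkn1a fell by 1.44 ± 0.15 and 1.06 ± 0.09 on the log2 scale. In the retinoic acid list 7 of 12 rose and 4 fell, with the receptor gene Rarb at 0.93 ± 0.10 and the retinoic acid synthesis gene Aldh1a3 at -1.66 ± 0.24, which did not pass with ROSA+/Notch dams only (-1.06, adjusted p = 0.053). The Hedgehog target Ptch1 rose by 0.74 ± 0.08 while Hhip, an inhibitor of the pathway, fell by 1.29 ± 0.18. Egr1, an immediate early gene, rose by 1.22 ± 0.11. None of these lists passed camera at the preset correlation.

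Genes at least 2-fold higher in Notch-induced E13.5 ovaries were often highest in perivascular-like cells at E16.5, among those with 50 CPM or more in some class. Only 162 of the 707 genes higher by at least 2-fold reached that level. Of these, 73 (45.1%) were highest in perivascular-like cells, against 7.63% of 6970 genes tested in bulk at that level. Of the 753 genes lower by at least 2-fold, 133 reached it. Of these, 48 (36.1%) were highest in pre-granulosa-like cells, against 14.6% of those 6970, and 33 (24.8%) in erythroid-like cells, against 4.02%. Heyl (143 CPM), AW011738 (44.0 CPM), Hey2 (37.2 CPM), Zfp663 (20.6 CPM) and Vgll3 (20.0 CPM) were highest in perivascular-like cells. Chst9, which rose, was highest in pre-granulosa-like cells at 117 CPM, and Lefty2 had no UMI in any named class. Col28a1 (3.13 CPM), Lefty1 (2.07 CPM), Iqsec3 (1.54 CPM) and Cnmd (1.26 CPM), which also rose, were highest in other classes, at low levels. Calb1 (131 CPM), Bhlhe41 (72.4 CPM), Ablim3 (33.0 CPM) and Hsd3b1 (30.1 CPM), which fell, were highest in pre-granulosa-like cells. The ages differ, and this comparison was made after the values were seen.

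Reporter UMIs were unevenly spread over the cells of a class. Among interstitial progenitor-like cells, 65 held 2 or more of the 246 reporter UMIs, where spreading them at random over the UMIs of the class would give 10.3 such cells. Among endothelial-like cells, which had 440 reporter UMIs in 233 cells, 66 held 2 or more, against 91.9.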
